A study of Homo sapiens with 7 samples.

How the data were processed

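The deposited files held a matrix of counts per library, that is UMI counts of 36601 features per cell barcode, per the file headers. Per the submitters' processing notes, these were made with Cell Ranger 6.0 on the GRCh38 genome and handled with Seurat 5.0.0, and the annotation version is not given in the sources used here. All deposited values were whole numbers, and the lowest barcode total was 500 UMIs in every library. Per the labels, 3 channels or 3 wells, with about 50 organoids per well, were pooled for the day 17 chip conditions and the well condition. Pooling was not stated for the day 6 and day 10 chip libraries. Each group therefore had 1 library, and groups were taken from the labels. Per the labels, libraries were made with kit v3.1 or v4 without a statement for each library. Gene coordinates came from GENCODE release 29 on GRCh38, joined by Ensembl ID, which matched 34616 of the 36601 features.

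Cells were kept with at least 1000 UMIs, at least 500 genes and at most 20% mitochondrial UMIs. Doublet scores came from Scrublet in Scanpy 1.11.5. Its automatic threshold marked 0, 0, 1, 2, 0, 1 and 0 cells and so did not work on these libraries. The highest-scoring share of barcodes was removed instead, at 0.4% per 1000 deposited barcodes, which took out 91, 419, 739, 769, 314, 605 and 1491 cells. This left 4206 cells at day 6, 9442 and 12085 at day 10 in wells and on chip, 12714 in wells at day 17, 8049 under low flow, 10896 under high flow and 16849 in the heart organoid library. Their median depths were 8903.5, 5958, 5150, 4100, 6300, 5673 and 3975 UMIs, and their median mitochondrial percents 2.54, 3.17, 3.09, 2.14, 2.02, 3.65 and 4.55.

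Each library was clustered on its own, with counts scaled to the median total, log transformation, 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering (igraph 0.11.9) at resolution 1. Of 111 clusters, 77 were named. A cluster took the name of a cell type when at least 3 of its markers were enriched 3-fold and detected in 10% of cells, and made up at least 25% of the type's markers (20% for mural-like). A cluster was mesenchymal-like when 12 of 30 mesenchymal markers reached 20 CPM and no other type was named. Of the 34 unnamed clusters, 14 had mesenchymal markers but were kept out because their 10 leading genes held more markers of another type. Clusters with a median depth that was more than 3 times below that of their library, and with none of their own markers among the leading genes, also stayed unnamed. A heart organoid cluster of 340 cells with a median of 1502 UMIs did not reach that bound and was named mesenchymal-like, although no mesenchymal marker was among its leading genes. The clusters kept out held 17.3%, 12.0%, 13.2%, 14.4%, 15.6% and 19.8% of kept cells from the day 10 well to the heart organoid library, and none at day 6. The thresholds for naming were set after the clusters had been looked at. The filters, comparisons, gene lists, size rule, rule for named genes and 21 alternative settings were fixed before the data were examined. The split of the contractile and pericyte lists by mural-like and other mesenchymal-like clusters was added after the data had been seen. The class names describe expression in these clusters and rest on no other measurement.

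Counts were summed over the cells of a class in each library and scaled to the class total as CPM. Ratios used 0.5 added to each count, with an exact conditional binomial 95% interval for a pair of Poisson counts. A gene passed the size rule with at least 20 CPM in the higher library, at least a 2-fold ratio and an interval that excluded no change. No test, p-value or standard error was given, because each group had 1 library, and a count of genes describes these libraries, not the conditions. Comparisons were made in classes of at least 50 cells for 9 pairs of libraries, of which 4 were the main ones and 4 compared days. Named genes were the 10 with the largest ratio in each direction (5 in the time and heart organoid comparisons) among genes with at least 50 CPM in the higher library and at least 0.5 of the level of that library's other cells. Mitochondrial, ribosomal protein, haemoglobin, Y-linked and clone-like symbols and XIST were left out. Members of the gene lists that passed were added as examples, and flow and arterial genes were given whatever their size. Some genes that met the rule are not reported here.

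For 34 gene lists, the median log2 ratio of members with at least 5 CPM was set beside 10000 random lists of the same size matched in 20 expression bins. Members of the random lists were drawn independently, so their range does not account for list members that vary together. Some genes are in more than 1 list, such as PGK1 and LDHA in glycolysis and hypoxia, so lists are not independent. For 2 chip libraries set against 1 well library, 100 simulations of unchanged groups gave the overlap and covariance that counting error in a shared control brings. Differences particular to that well library were not simulated. Shares of cells with a UMI were computed after thinning each cell to 2000 UMIs, and shallower cells were left out. Shares have exact (Clopper-Pearson) binomial intervals. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, with a fixed seed.

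Simulated data at the depth of the high-flow and low-flow libraries, with 200 genes changed, carried counting error only and no variation between libraries. The size rule was tested on them. It called 0% of genes changed 1.5-fold, 99% (endothelial-like) and 100% (mesenchymal-like) of genes changed 2.5-fold and 100% of those changed 4-fold, and no unchanged gene. Intervals covered the true ratio for 94.5% to 98.5% of changed genes. The 21 alternative settings covered cell filters, doublet removal, cluster resolution, joint clustering, class by cell, scaling, expression and fold thresholds, the added count, cells carrying markers of the other class, proliferating cells and thinning. One alternative, which kept the 14 clusters in the mesenchymal-like class, was added after the data had been seen.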

Results

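Single-cell RNA was counted in 7 libraries of organoids grown from the human induced pluripotent stem cell line WTC. Vascular network organoids (VNOs) hold endothelial cells, which line vessels, together with mesenchymal cells that surround them. They were sampled at day 6, at day 10 in wells or on a microfluidic chip, and at day 17 in wells or on a chip under low flow or under high flow. The seventh library came from vascularized heart organoids kept on a chip under high flow. Each group had 1 library, so no value below has a replicate check, and the 95% intervals cover counting error of molecules (unique molecular identifiers, UMIs) or of cells only. The deposited barcodes numbered 5280 at day 6, 10611 and 14399 at day 10 in wells and on chip, 14256 in wells at day 17, 9392 under low flow, 13151 under high flow and 20326 in the heart organoid library. Their total counts in the same order were 48086070, 74815016, 81677023, 73011187, 63326578, 77315882 and 98253883 UMIs. Kept cells had median depths between 3975 UMIs in the heart organoid library and 8903.5 UMIs at day 6. The day 6 title calls its library VNOs and adds "MVP agg.", which is not explained, so that it came before the others in the same culture was assumed. The labels name a pair of kit versions without saying which library used which, so kit, depth and condition cannot be separated.

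Endothelial-like cells, named from clusters enriched for vessel genes such as PECAM1, CDH5 and CLDN5, were found in every library. They made up 6.56% of kept cells at day 6 (5.83 to 7.35, exact binomial interval) and 16.0% (15.3 to 16.8) at day 10 in wells. The day 10 chip library held 6.77% (6.33 to 7.23). At day 17 the shares were 4.90% (4.53 to 5.29) in wells, 4.57% (4.13 to 5.05) under low flow and 3.56% (3.22 to 3.93) under high flow. The heart organoid library held 4.44% (4.13 to 4.76). These shares depended on how cells were kept and named. At day 6 the share was 7.69% with a stricter cell filter, 10.1% when each cell was named by itself, 11.2% with all libraries clustered together and 12.0% with a looser cell filter. The share in wells at day 17 was 2.44% at resolution 2 and 6.43% when each cell was named by itself. In the heart organoid library it was 3.49% with the stricter filter and 8.47% when each cell was named by itself. The class was 1 cluster per library, except at day 10 in wells, where clusters 5 and 10 held 1089 and 426 cells. The second of these had 5 of the 19 endothelial markers enriched, with EDN1 and TFPI2 among its leading genes. Median depths of the endothelial-like cells were 18344.5, 7410, 6205, 8167, 6427, 8827 and 3272.5 UMIs in the order of the libraries given above. Depth per cell thus differed between libraries, and the cause was not tested.

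**Figure D1:**
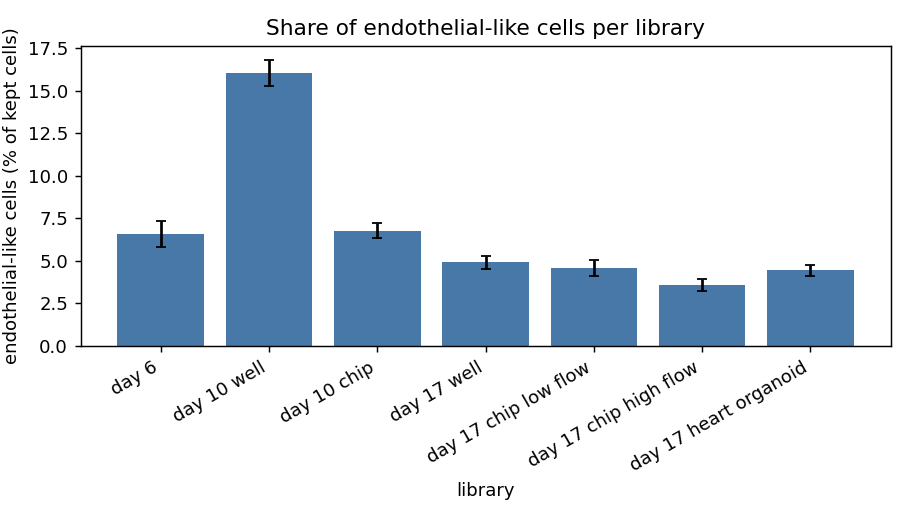
Bars show endothelial-like cells as a percent of kept cells (vertical axis) in each of the 7 libraries (horizontal axis), and error bars are exact 95% binomial intervals. The day 10 well library stood at 16.0%, and the other libraries lay between 3.56% and 6.77%. Settings that moved a share out of its interval, not drawn here, gave 7.69% to 12.0% at day 6, 15.2% to 17.3% and 7.81% to 8.64% at day 10 in wells and on chip, 2.44% and 6.43% in day 17 wells, 5.09% under low flow, 4.00% and 4.30% under high flow, and 3.49% to 8.47% in the heart organoid library.

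Mesenchymal-like cells, which expressed collagen and mural genes, made up 24.7% of kept cells at day 6, 63.4% and 69.3% at day 10 in wells and on chip, and 81.9%, 77.0% and 74.3% at day 17 in wells, under low flow and under high flow. Their share was 64.7% in the heart organoid library. With all libraries clustered together the share was 0.404% at day 6, and 22.5% in wells and 38.4% under low flow at day 17. The day 6 share was also 7.88% with the looser filter and 11.4% at resolution 0.5. Of the 22 joint clusters, 10 took 75% or more of their cells from 1 library, and 9 of these were among the 15 that were mesenchymal-like or were kept out of that class for their leading genes. The other was cardiomyocyte-like. Mesenchymal comparisons below therefore include cells that fell into different joint clusters by library, and cell state, library and condition cannot be separated in them. Clusters rich in contractile and pericyte genes, called mural-like here, held 5.84% of kept cells at day 10 in wells and 15.4% on chip, and 12.0%, 18.9% and 9.35% at day 17 in wells, under low flow and under high flow. The heart organoid library held 14.8%. With joint clustering, the mural-like clusters 4 and 18 held 1293 and 65 of 12714 kept cells in day 17 wells. They held 2118 and 29 of 8049 under low flow and 1593 and 5 of 10896 under high flow. In the heart organoid library they held 166 and 1037 of 16849. At day 10 they held 7 and 532 of 9442 in wells and 15 and 1090 of 12085 on chip. The high-flow share then lay above those of day 17 wells and heart organoids, so the order depended on the clustering. No mural-like cluster was named at day 6, where 68.2% of cells stayed without a name. Unnamed shares in the other libraries ran from 13.2% to 27.5%. A cardiomyocyte-like cluster was named in the heart organoid library alone, with 270 cells or 1.60% of kept cells (1.42 to 1.80).

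The day 10 comparison set organoids on the chip against organoids kept in wells. In the endothelial-like class, 107 genes were higher and 21 lower in the chip library by the size rule. EFNA5, an ephrin ligand, stood at 54.2 against 13.9 CPM (counts scaled to the class total), 3.91-fold (3.27 to 4.69). PLAUR, the urokinase receptor, was 3.71-fold higher (3.27 to 4.22). HMOX1, a haem-degrading enzyme, was 2.90-fold higher (2.59 to 3.26), and IGFBP5, which binds insulin-like growth factors, stood at 396 against 137 CPM. PLAUR (ENSG00000011422) lies on chromosome 19 from 43646095 to 43670547, and EFNA5 (ENSG00000184349) on chromosome 5 from 107376889 to 107670895 in GRCh38. SGMS2, ARG2, AREG, IRS2 and ARID5A were 3.81-, 3.64-, 3.26-, 3.24- and 3.02-fold higher. The lower side held PCAT14 (2.56-fold), HIST1H1B (2.29-fold), and ITGA6 (2.07-fold), a laminin receptor subunit.

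Of 12 measured genes known to be reduced by steady flow, 6 were higher, 0 lower and 6 neither in the day 10 chip endothelial-like cells, with a median log2 ratio of 0.78. Among them ANGPT2, a vessel-destabilizing ligand, stood at 263 against 114 CPM (2.31-fold, 2.16 to 2.48), and CCN2 at 218 against 93.4 CPM (2.33-fold). ANKRD1 was 4.41-fold higher (3.60 to 5.44). The list of genes induced by laminar flow had a median of 0.49, with 1 of 15 higher and 0 lower, and KLF2, a flow-responsive transcription factor, had a log2 ratio of 0.49 (0.37 to 0.61). Sprouting genes had 3 of 16 higher, among them PGF at 4.53-fold (3.70 to 5.60), while the median of that list was 0.18. Arterial genes had a median of 0.21 with none of 18 passing the size rule. Hypoxia genes had 2 of 18 higher, of which DDIT4 was 4.95-fold and ENO2 3.44-fold higher. The immediate early list had 2 of 14 higher, with ATF3 at 344 against 145 CPM. All these medians lay above the central 95% of matched random lists. Of 33 lists in this comparison 13 lay above and 4 below this range, so a place outside it was common. The cell cycle list had a median of -0.58 with none of 22 passing, below that range. Without cells that had a proliferation marker that median was 0.15.

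In the mesenchymal-like class 37 genes were higher and 25 lower on the chip at day 10. ACTC1, a muscle actin, stood at 101 against 7.52 CPM (13.4-fold, 11.9 to 15.1). ACTA2, smooth muscle actin, was 3.78-fold higher (3.61 to 3.96) and TAGLN, an actin-binding protein of smooth muscle, stood at 737 against 243 CPM (3.04-fold). The contractile list had 3 of 10 higher, 0 lower and a median of 0.92. The chemokines CCL2 and CCL7 were 4.68- and 3.49-fold higher, and SFRP2, which modulates Wnt signalling, 3.79-fold. On the lower side, SFRP1, a relative of SFRP2, stood at 274 against 735 CPM (2.68-fold), PTN was 2.60-fold lower, BIK 4.65-fold and RGS2 3.02-fold. The immediate early list had 2 of 14 lower and a median of -0.47, with FOS at 120 against 330 CPM and FOSB 2.42-fold lower. The share of mural-like cells in the class differed between these libraries, and the contractile median was 0.58 inside mural-like clusters and 0.17 in the other mesenchymal-like clusters. With clusters kept out for their leading genes taken back into the class, 31 genes were higher and 46 lower.

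At day 17 the chip library under low flow was set against the well library of the same day. In endothelial-like cells 102 genes were higher and 135 lower. The larger side turned at 1.5-fold (486 and 430) and without cells that had a proliferation marker (117 and 102). TXNIP, a regulator of thioredoxin and glucose uptake, stood at 225 against 43.6 CPM (5.16-fold, 4.50 to 5.95). Its gene (ENSG00000265972) lies on chromosome 1 from 145992435 to 145996600. TSTD1 was 5.69-fold higher (4.42 to 7.44). The heat shock genes HSPA1A and HSPA1B, near-identical copies whose split is uncertain, were 5.04- and 2.96-fold higher, and the matrix genes COL11A1 and BGN 3.08- and 3.06-fold. FAM124B, INHBB and CREG2 were 4.02-, 3.81- and 3.41-fold higher. On the lower side, CARTPT, a neuropeptide precursor, stood at 12.6 against 380 CPM (29.7-fold, 21.9 to 42.4). CCL2 was 5.78-fold lower (4.65 to 7.36) and CYP1B1, an oxidase gene in the laminar flow list, 4.58-fold (3.90 to 5.44). H19, PCLAF, TBX3, ACSM3 and MT2A were 7.70-, 7.34-, 5.65-, 4.72- and 4.58-fold lower, and ITGA6 was lower as at day 10.

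Proliferation genes were lower as a group in this endothelial comparison, with 12 of 22 lower, 0 higher and a median log2 ratio of -1.77. MKI67 stood at 5.51 against 40.2 CPM (7.10-fold, 4.47 to 12.7) and TOP2A, a topoisomerase of dividing cells, at 6.48 against 38.0 CPM (5.74-fold, 3.72 to 9.78). Cholesterol synthesis genes had 5 of 16 lower with a median of -0.83, among them HMGCS1 (2.71-fold) and INSIG1 (2.73-fold). Inflammatory genes had 3 of 11 lower with a median of -0.73, among them CXCL2 at 47.0 against 163 CPM. Venous genes had 3 of 6 lower, of which NR2F2, APLNR and TSPAN7 were 4.32-, 4.84- and 5.25-fold lower. NR2F2 was seen in a larger share of mesenchymal-like cells, as given below, and RNA from other cells was not excluded as its source. Sprouting genes had 3 of 16 higher with a median of 0.44, namely ANGPT2 (2.01-fold), PGF (2.84-fold) and ADM (2.03-fold). Hypoxia genes had 4 of 18 higher with a median of 0.35, including ENO2 (3.24-fold) and NDRG1 (2.30-fold), and heat shock genes 3 of 11 with a median of 0.56. Flow-related genes went both ways. KLF4 stood at 57.0 against 120 CPM, 2.09-fold lower (1.78 to 2.48), and KLF2 had a log2 ratio of 0.31 (0.17 to 0.44). In the other cells of these libraries KLF4 stood at 35.2 CPM in wells and 25.3 CPM under low flow, and KLF2 at 92.1 and 35.2 CPM. Both were among the leading genes of a mesenchymal-like well cluster of 865 cells, beside FOS and EGR1. An immediate early response and flow cannot be told apart for these genes. The laminar flow list had a median of -0.30 with 2 of 16 lower. The arterial list had a median of 0.20, with SEMA3G at 0.98, CXCR4 at 0.73 and GJA4, an arterial gap junction gene, at 0.28, while GJA5 was at -0.53 (-0.74 to -0.34).

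In mesenchymal-like cells 144 genes were higher and 164 lower under low flow than in the well. Smooth muscle genes were higher as a group, with 8 of 15 contractile genes higher, 0 lower and a median log2 ratio of 1.67. Mural-like clusters held 18.9% of kept cells under low flow against 12.0% in wells. The contractile median was 0.90 inside mural-like clusters and 2.02 in the other mesenchymal-like clusters. Mural-like clusters were named by enrichment of mural genes over the other cells of the same library. Contractile cells can therefore remain in the other clusters, where ACTA2 is high throughout. Outside mural-like clusters ACTA2 stood at 428 CPM under low flow against 55.3 CPM in wells. This split therefore cannot decide whether the mix of cells was the cause. ACTA2 stood at 1380 against 434 CPM (3.19-fold), and TAGLN, MYH11 and MYL9 were 3.21-, 4.19- and 3.58-fold higher. NPR3, a natriuretic peptide receptor, was 16.1-fold higher (13.9 to 18.9), and MGP, matrix Gla protein of vessel walls, stood at 835 against 109 CPM (7.68-fold, 7.47 to 7.90). HOPX, SPP1, COL8A1, NNMT and SLC5A7 were between 9.37- and 11.5-fold higher, and MYLK, LYPD1 and ANKRD1 6.13-, 5.99- and 5.69-fold. Basement membrane genes had 3 of 12 higher (COL4A1 2.62-fold, COL18A1 3.31-fold), and interstitial matrix genes 4 of 19 (COL1A1 2.41-fold, LOX 3.18-fold). SFRP1, ALDH1A2, HAND2, TAC1, HAS2 and NTRK2 were 14.6-, 11.3-, 8.76-, 8.42-, 7.21- and 5.97-fold lower. Low-flow clusters of 733 and 280 cells, with ALDH1A2 and TAC1 among their leading genes, were kept out of the class. A well cluster of 1672 cells with SFRP1 and ALDH1A2 in the lead was kept out too. ALDH1A2 stood at 15.1 CPM in the low-flow class and 46.1 CPM in that library's other cells, against 171 and 141 CPM in wells. The size of its ratio thus depended on which clusters were named. The cardiac mesoderm factors had 3 of 5 lower with a median of -1.71. The higher genes were 46.8% of those passing, and 57.0% with median-of-ratios scaling, so neither side can be called the larger.

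High flow against the same day 17 well library gave 154 higher and 154 lower genes in endothelial-like cells. EDNRB, an endothelin receptor, stood at 52.6 against 7.52 CPM (6.95-fold, 5.13 to 9.72). NQO1, a quinone reductase of the oxidative stress response and a member of the laminar flow list, stood at 162 against 35.5 CPM (4.55-fold, 3.92 to 5.31). SLC7A11, a cystine transporter, was 3.51-fold higher, and ANKRD37, TSTD1, COL11A1, GDF15, GAB1, DDIT4 and ANGPTL4 were between 2.96- and 4.89-fold higher. PCLAF was 9.40-fold lower, MT2A, a metallothionein, 8.77-fold, CARTPT 6.60-fold and CCL2 3.97-fold (3.37 to 4.73). FN1, fibronectin, stood at 147 against 613 CPM (4.18-fold, 3.84 to 4.56). H19, IL32, NNAT and CENPW were 4.33-, 4.32-, 3.83- and 3.53-fold lower.

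The cell cycle list was again lower, with 14 of 22 lower, 0 higher and a median log2 ratio of -2.24 in the high-flow endothelial-like cells. TOP2A stood at 4.36 against 38.0 CPM (8.50-fold, 5.40 to 14.9). RRM2 was 14.7-fold and MKI67 6.26-fold lower. Inflammatory genes had 4 of 10 lower with a median of -0.59, including CXCL1 (2.30-fold), CXCL2 (2.48-fold) and BIRC3 (2.33-fold). Sprouting genes had 2 of 15 higher with a median of 0.67, PGF at 2.36-fold and ADM at 2.01-fold. Basement membrane genes had a median of 0.72 with none of 13 passing. Fatty acid genes had 3 of 11 higher and 1 lower with a median of 0.64, among them CPT1A, which brings fatty acids into mitochondria, at 5.32-fold and the lipid droplet gene PLIN2 at 2.56-fold. Glycolysis genes had 2 of 15 higher (HK2 2.44-fold, PFKFB3 2.07-fold) and 3 lower (ENO1 2.09-fold, PKM 2.01-fold, LDHA 2.00-fold), with a median of -0.39. KLF4 was 2.03-fold lower, and KLF2 had a log2 ratio of 0.24 (0.11 to 0.36). In the other cells KLF4 stood at 35.2 CPM in wells and 22.7 CPM under high flow, and KLF2 at 92.1 and 39.9 CPM. The limit given for these genes under low flow holds here too. The laminar flow list had a median of 0.23 with 1 of 16 higher and 1 lower. Within the arterial list GJA4 had a log2 ratio of 0.74 (0.66 to 0.83), CXCR4 of 0.89 and IGFBP3 of 0.84, while GJA5 had -0.79 (-0.99 to -0.60), and the list median was 0.13. Contractile genes had 3 of 9 lower, with TAGLN in endothelial-like cells of the well library at 0.28 of its level in that library's other cells. Whether this RNA came from the endothelial-like cells was not determined.

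In mesenchymal-like cells 97 genes were higher and 101 lower under high flow than in the well. NQO1 stood at 63.4 against 7.37 CPM (8.60-fold, 7.75 to 9.59) and FABP4, a fatty acid-binding protein, at 65.9 against 7.92 CPM (8.31-fold, 7.52 to 9.23). CALCB, PDE1A, ANGPTL4, NEFL and PLIN2 were between 3.23- and 4.71-fold higher, and APOE, TKT and FST 2.76-, 2.73- and 2.53-fold. Fatty acid genes had 4 of 11 higher with a median log2 ratio of 0.70, CPT1A being 4.71-fold higher. Glycolysis genes had 5 of 15 lower with a median of -0.85, and ENO1, the enolase gene, stood at 402 against 1340 CPM (3.33-fold, 3.28 to 3.38). YAP target genes had 4 of 13 lower with a median of -0.40, of which CCN1 stood at 18.3 against 91.0 CPM (4.96-fold). PTX3, TXNIP, TAC1, TNC and NTRK2 were 7.64-, 4.54-, 4.31-, 4.04- and 3.23-fold lower. The cell cycle list had a median of 0.45 with none of 22 passing, opposite in sign to the endothelial-like class. Higher genes were 49.0% of those passing, and 62.8% with median-of-ratios scaling. With the class from the joint clustering 134 were higher and 293 lower, so the larger side was not fixed.

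The direct comparison of high with low flow gave 147 higher and 73 lower genes in endothelial-like cells. NQO1 stood at 162 against 22.0 CPM (7.29-fold, 5.71 to 9.57). CYP1B1 and CYP1A1, oxidases induced through the aryl hydrocarbon receptor, were 2.80-fold (2.35 to 3.36) and 2.61-fold (2.03 to 3.41) higher. STARD4, a cholesterol transport gene, stood at 94.1 against 25.6 CPM (3.66-fold, 2.88 to 4.74). Its list, cholesterol synthesis, had 9 of 16 higher, 0 lower and a median log2 ratio of 1.15, with MSMO1 at 2.74-fold and SREBF2, the sterol-sensing transcription factor, at 2.42-fold. CARTPT, PLAU, ANKRD37, PRND, TIMP2, TKT, SLC7A11 and RCAN1 were between 3.19- and 4.50-fold higher. Capillary genes had 2 of 9 higher with a median of 1.06, and the laminar flow list 3 of 16 higher with a median of 0.35. HSPA1A was 6.74-fold lower (5.54 to 8.30) and HSPA1B 5.56-fold, with the uncertain split noted above. The heat shock list had 4 of 11 lower and a median of -0.72. TXNIP was 4.99-fold lower (4.25 to 5.91), and IGFBP5 stood at 189 against 897 CPM (4.75-fold, 4.39 to 5.15). NNAT, PCAT19, TMEM233, AK4, ARG2 and FN1 were between 2.78- and 4.17-fold lower. Glycolysis genes had 1 of 15 higher and 1 lower with a median of -0.69, where LDHA, lactate dehydrogenase, stood at 340 against 829 CPM. Hypoxia genes had 3 of 18 lower and 1 higher with a median of -0.49. Averaging CPM over cells, so that deep cells weigh no more than shallow ones, moved the share of higher genes among those passing from 66.8% to 53.5%. At 1.5-fold 456 genes were higher and 483 lower.

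The flow genes KLF2, KLF4 and NOS3 and the arterial genes GJA4 and GJA5 did not pass the size rule between the flow rates. KLF2 had a log2 ratio of -0.07 (-0.22 to 0.07), KLF4 of 0.04 (-0.24 to 0.33) and NOS3, endothelial nitric oxide synthase, of -0.07. GJA4 was at 0.46 (0.36 to 0.56) and GJA5 at -0.25 (-0.50 to -0.01). The arterial list had a median of -0.08, inside the range of matched random lists.

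In mesenchymal-like cells 116 genes were higher and 150 lower under high than under low flow, and 156 and 268 with the class from the joint clustering. FABP4 stood at 65.9 against 0.892 CPM, 73.0-fold higher (54.7 to 102). The fatty acid list had 5 of 11 higher with a median log2 ratio of 0.87, including CD36 (7.32-fold), CPT1A (4.48-fold), PPARG (2.58-fold) and PLIN2 (2.26-fold). SFRP1, ALDH1A2, PDE1A, CALCB and NQO1 were 9.38-, 8.10-, 7.82-, 6.21- and 3.90-fold higher. Low-flow clusters of 733 and 280 cells, with ALDH1A2 among their leading genes, were kept out of the class. ALDH1A2 stood at 122 CPM in the high-flow class and 91.4 CPM in that library's other cells, against 15.1 and 46.1 CPM under low flow. SFRP1 stood at 220 and 120 CPM under high flow, against 23.4 and 43.7 CPM under low flow. The size of these ratios thus depended on which clusters were named. Contractile genes were lower as a group, with 9 of 15 lower, 0 higher and a median of -1.38. ACTC1 stood at 6.95 against 104 CPM (a ratio between 13.5 and 16.7), and TAGLN, MYL9 and ACTA2 were 4.25-, 3.97- and 2.99-fold lower. Glycolysis genes had 12 of 15 lower, 0 higher and a median of -1.16. PGK1, ENO1, LDHA and GAPDH were 3.02-, 3.05-, 2.97- and 2.37-fold lower, and SLC16A3, a lactate exporter, stood at 8.80 against 52.6 CPM. Hypoxia genes had 6 of 19 lower with a median of -0.96, and the hypoxia-related mural gene NDUFA4L2 was 16.0-fold lower. PGK1 and LDHA are members of both the glycolysis and the hypoxia list, so these results are not separate. Interstitial matrix genes had 6 of 20 lower and 1 higher, and YAP targets 4 of 14 lower, with CCN2 at 4.37-fold. COL8A1, ACTG2, NPR3, MGP, TXNIP, ANKRD1 and HOPX were between 4.55- and 14.1-fold lower. The low-flow library also had the higher share of mural-like cells, 18.9% against 9.35%, and the contractile median was -0.77 inside mural-like clusters and -1.41 in the other mesenchymal-like clusters. Summed glycolysis CPM ran from 2581.91 to 4813.71 over the 11 high-flow mesenchymal-like clusters and from 6526.85 to 10130.7 over the 10 low-flow ones.

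**Figure D2:**
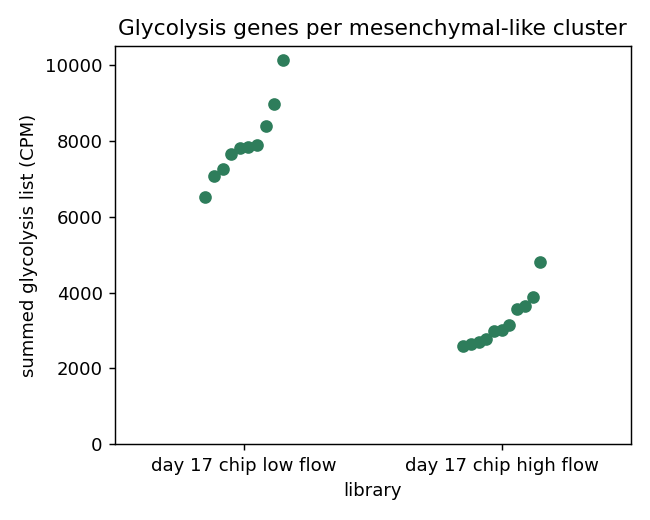
Each point is 1 mesenchymal-like cluster of the low-flow or high-flow day 17 chip library (horizontal axis), and the vertical axis is the CPM summed over the glycolysis list. Clusters under high flow (median 3023.46 CPM) all lay below those under low flow (median 7829.62 CPM).

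**Figure D3:**
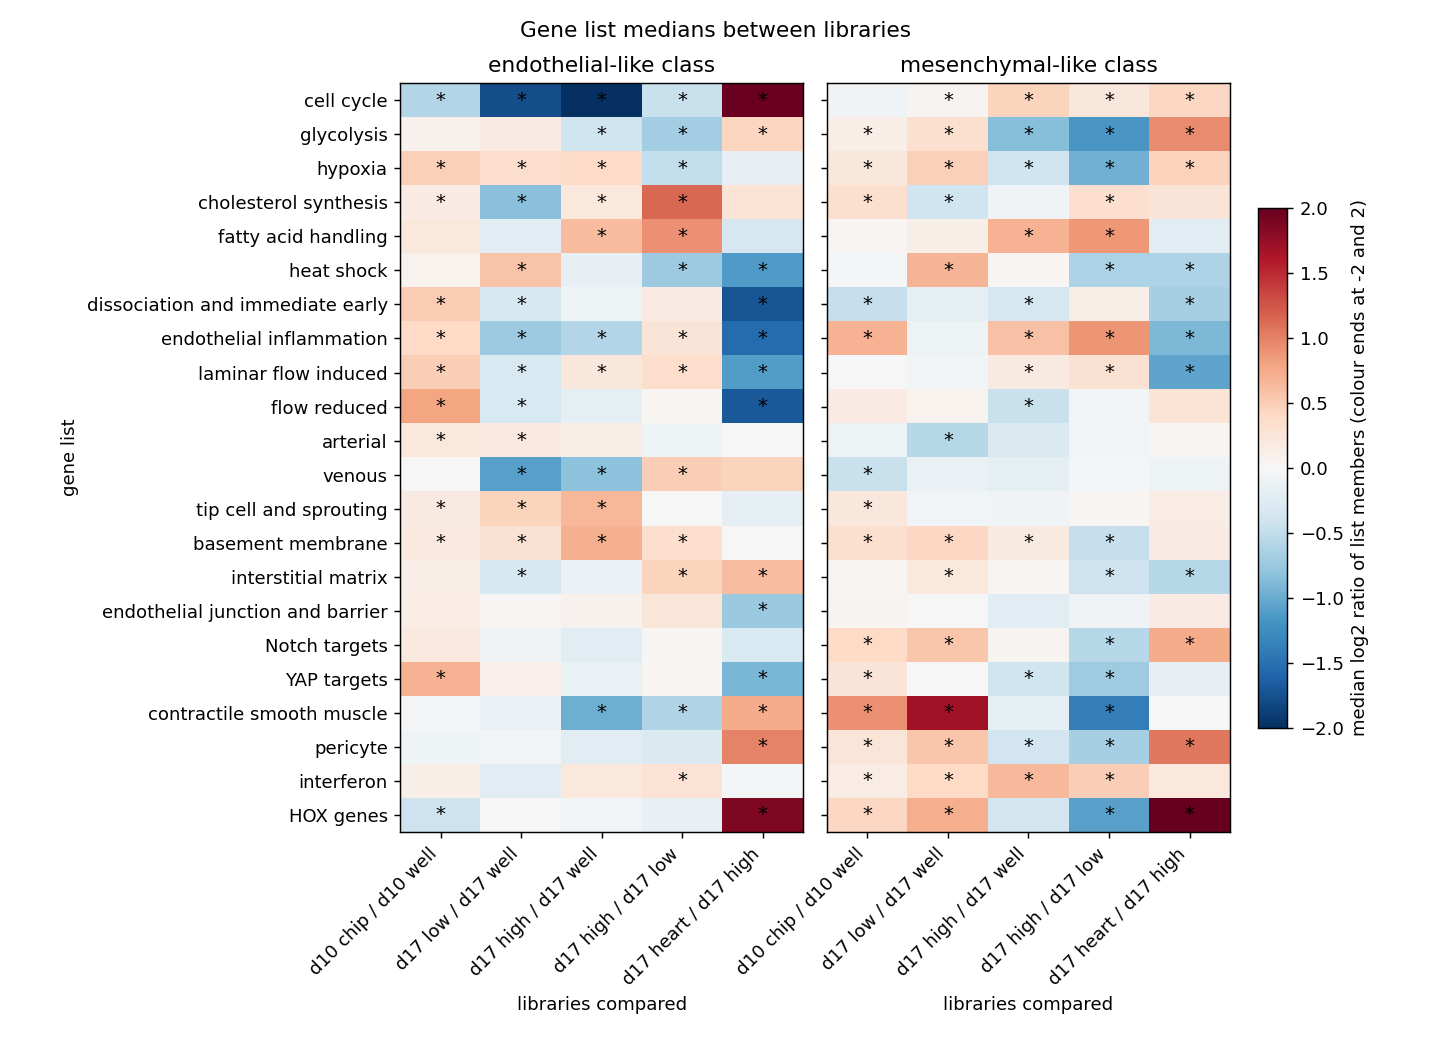
Colours give the median log2 ratio of a gene list (vertical axis, 22 lists) for 5 pairs of libraries (horizontal axis) in the endothelial-like and mesenchymal-like class, with colours ending at -2 and 2. Stars mark medians outside the central 95% of 10000 matched random lists, such as cell cycle at -2.24 and contractile genes at 1.67. Such medians were common, with 13 of 33 lists above and 4 below that range in the day 10 endothelial comparison.

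Overlap between these comparisons was counted by direction. Chip against well at day 10 and low flow against well at day 17, which share no library, had 16 endothelial genes passing in the same direction where 0.769 would be met by chance, and 10 in opposite directions. For high flow these counts were 16 (chance 1.46) and 6. In the mesenchymal-like class the counts were 33 (chance 0.808) and 3 for low flow, and 10 (chance 0.461) and 5 for high flow. These chance values are for the same direction only, and none was computed for opposite directions. An excess in the same direction alone therefore does not show a shared response to the chip. Low and high flow against the same well library shared 109 of 6368 endothelial genes in direction (chance 4.52) and 64 mesenchymal genes (chance 3.53). Simulated groups without change gave 0 such genes, but they carried counting error only. A shift particular to the shared well library was not simulated. Across genes, the log2 ratios had a covariance of 0.138 in endothelial-like cells (0.00734 simulated) and 0.105 in mesenchymal-like cells (0.000875 simulated). Pearson correlations across genes, which are not independent replicates, were 0.604 (0.376 simulated) and 0.574 (0.495 simulated). Part of the excess may come from the shared control library.

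Endothelial-like cells at day 10 in wells, set against day 6, had 380 higher and 143 lower genes. PTGS2, prostaglandin synthase, stood at 67.8 against 2.84 CPM (23.2-fold), VEGFC, a vessel growth factor, 16.4-fold, TFPI2 13.0-fold, DUSP1 12.2-fold and FOS 10.2-fold. Arterial genes had 7 of 18 higher with a median log2 ratio of 0.75, among them GJA5 at 2.38 and GJA4 at 1.02. Notch targets had 4 of 9 higher with a median of 1.34. APLNR, the apelin receptor, was 5.87-fold lower (5.03 to 6.89), TXNIP 6.43-fold, DIO3 5.73-fold, ECM1 4.45-fold and KIF5C 4.36-fold. From day 10 to day 17 in wells, 210 genes were higher and 239 lower, and 249 and 189 with median-of-ratios scaling. RRAD was 20.9-fold, RCAN1 13.1-fold, CXCL2 9.97-fold, CXCL8 9.77-fold and NR4A2 6.62-fold higher, and the inflammation list had 6 of 10 higher. LPL, PCAT14, TMEM100, GAP43 and MMP9 were 16.5-, 13.8-, 6.39-, 6.05- and 5.35-fold lower. Cell cycle genes had 17 of 22 lower with a median of -1.37, and HOX genes, which mark position along the body axis, 8 of 12 lower with a median of -1.43.

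Between day 10 and day 17 on chip the endothelial cell cycle list had 20 of 22 lower under either flow rate, with medians of -2.75 under low and -3.24 under high flow. Low flow gave 210 higher and 362 lower genes, high flow 250 and 403. With median-of-ratios scaling the high-flow counts were 339 and 303. HSPA1A and HSPA1B were 17.3- and 10.4-fold higher under low flow, TXNIP 6.88-fold and DNAJB1 5.87-fold, while CARTPT, LPL, MMP9, CYP1B1 and GAP43 were between 8.39- and 15.3-fold lower. Under high flow ARC, ANKRD37, EDNRB, RCAN1 and CPXM2 were between 7.52- and 12.0-fold higher. MMP9, a matrix-degrading enzyme, was 37.0-fold lower (21.5 to 77.9), and GAP43, PRC1, MT2A and CDK1 were between 9.53- and 19.3-fold lower. Each of these pairs differs in day, library and possibly kit at once.

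Mesenchymal-like cells had 453 higher and 216 lower genes at day 10 in wells against day 6. Of the 1037 day 6 cells, 248 and 322 were in clusters with mostly cell cycle and histone genes in the lead, and the class held 17 cells with joint clustering. EMCN was 424-fold (186 to 1.75e+03), ITGA4 224-fold, FAR2 150-fold, DNM3OS 141-fold and BIK 120-fold higher. SST, the somatostatin gene, was 629-fold lower (339 to 1.55e+03), and KISS1, SMOC1, ROBO2 and SALL1 were between 10.7- and 61.5-fold lower. From day 10 to day 17 in wells 224 were higher and 237 lower, and 271 and 145 with the class from the joint clustering. MGP was 110-fold higher, TAC1 and PTX3 12.0-fold each and SCX 10.1-fold, with LIN28B 8.47-fold, DOK4 6.96-fold and HMMR 5.30-fold lower. Cell cycle genes had 15 of 22 lower and contractile genes 4 of 12 higher, while the mural-like share was 12.0% at day 17 against 5.84% at day 10. The contractile median was 1.52 inside mural-like clusters and 0.44 in the other mesenchymal-like clusters. On chip, low flow at day 17 had 277 higher and 382 lower genes than day 10, including MGP (178-fold), HOPX (28.2-fold) and COL12A1 (26.8-fold), with SFRP1 11.7-fold lower. High flow had 253 higher and 338 lower, including FABP4 (609-fold, 287 to 2.07e+03), MGP (26.5-fold) and CALCB (17.7-fold), with SFRP2 24.6-fold and ACTC1 14.5-fold lower. With median-of-ratios scaling these counts were 319 and 281 under low flow and 331 and 219 under high flow.

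Shares of cells with a UMI, after every cell was thinned to 2000 UMIs, put these genes on one depth. TOP2A was seen in 17.5%, 16.3% and 12.7% of endothelial-like cells at day 6, day 10 in wells and day 10 on chip. At day 17 the shares were 6.76% (4.81 to 9.20) in wells, 0.306% (0.00774 to 1.69) under low flow and 0.587% (0.0711 to 2.10) under high flow. Mesenchymal-like cells of the same day 17 libraries had 8.78%, 10.5% and 12.6%, and the unthinned endothelial shares were 11.4%, 3.53% and 3.35%. ESM1, a marker of sprouting endothelium, was seen in 24.2% of endothelial-like cells at day 6 and in 83.4% to 96.3% in the later libraries, against 0% to 2.41% of mesenchymal-like cells. Without thinning its endothelial shares were 47.8% at day 6 and 85.8% to 96.5% later. KLF2 was seen in 27.2% (23.5 to 31.2) in wells at day 17, 35.2% (29.995 to 40.6) under low flow and 33.1% (28.2 to 38.4) under high flow. The differences between these shares were not tested. KLF2 was also seen in 14.3%, 5.38% and 6.47% of mesenchymal-like cells there, and its unthinned endothelial shares were 57.3%, 61.4% and 66.0%. GJA4 was seen in 41.3%, 47.7% and 58.7% (69.7%, 73.6% and 81.7% unthinned) against under 1% of mesenchymal-like cells. NR2F2 was seen in 0% to 4.75% of endothelial-like cells of the VNO libraries and in 15.3% to 32.0% of mesenchymal-like cells, and the source of the endothelial counts was not determined. In the day 17 wells, under low flow and under high flow, median depths were 8167, 6427 and 8827 UMIs in endothelial-like and 4147, 6827 and 5712.5 UMIs in mesenchymal-like cells, and 76, 41 and 47 endothelial-like cells under 2000 UMIs were left out.

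**Figure D4:**
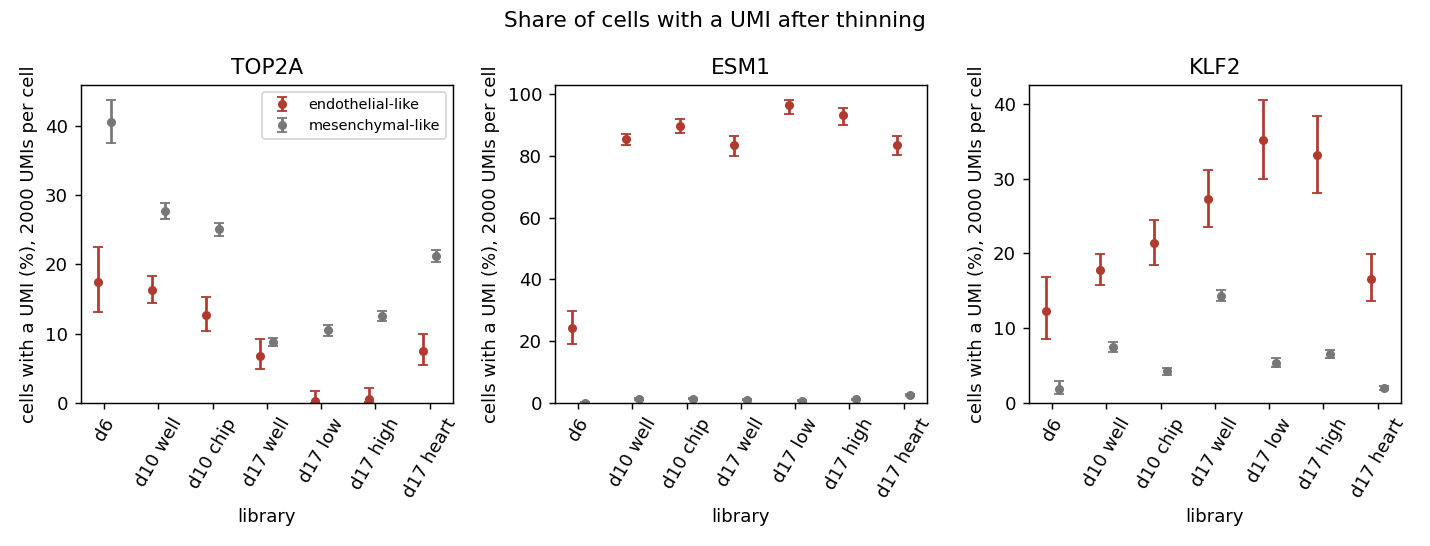
Points show the percent of cells with at least 1 UMI of TOP2A, ESM1 or KLF2 after thinning to 2000 UMIs (vertical axes) per library (horizontal axes), in endothelial-like and mesenchymal-like cells, with exact 95% binomial intervals. TOP2A in endothelial-like cells stood at 6.76% in day 17 wells and at 0.306% and 0.587% under low and high flow.

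The heart organoid library was set against high-flow VNOs to compare vessel cells between organoid types. In endothelial-like cells 270 genes were higher and 402 lower. The larger side turned at 5 CPM (928 and 661), at 1.5-fold (946 and 892) and without mitochondrial and ribosomal protein genes (407 and 401). Immediate early genes had 9 of 14 lower with a median log2 ratio of -1.73, among them ATF3 at 13.4 against 479 CPM (35.3-fold, 26.6 to 49.1). Inflammatory genes had 7 of 10 lower with a median of -1.54, and CXCL8 had 1 count against 292, a ratio of 158 (42.2 to 9.4e+03). Laminar flow genes had 9 of 16 lower with a median of -1.12. KLF2 stood at 98.6 against 216 CPM (2.19-fold) and KLF4 at 3.88 against 58.7 CPM (14.6-fold, 8.67 to 28.8), while CYP1B1 was 46.7-fold lower (26.4 to 103). NR4A3 and AREG were 27.1- and 25.2-fold lower. Cell cycle genes had 10 of 21 higher with a median of 1.98, with TOP2A at 48.4 against 4.36 CPM. HOX genes had 9 of 15 higher with a median of 1.86, including HOXC6 (9.27-fold), HOXB3 (5.16-fold) and HOXA9 (4.12-fold). GAP43, a growth cone protein, was 8.20-fold higher (6.21 to 11.2), and PHF23, PRTG, NBEAL1 and MYL9 were between 3.43- and 4.72-fold higher. The heart organoid endothelial-like cells were shallower, with 3272.5 against 8827 UMIs at the median.

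In mesenchymal-like cells 243 genes were higher and 380 lower in the heart organoid library. HOX genes had 11 of 19 higher, 0 lower and a median log2 ratio of 2.21, with HOXB9 at 164 against 23.1 CPM (7.09-fold) and HOXC9 at 6.69-fold. PLVAP was 14.2-fold and SPP1 7.93-fold higher. Pericyte genes had 5 of 12 higher with a median of 1.05, while mural-like clusters held 14.8% of kept cells against 9.35% under high flow. This order of mural-like shares turned with joint clustering, as given above. The pericyte median was 0.59 inside mural-like clusters and 1.80 in the other mesenchymal-like clusters. Glycolysis genes had 6 of 15 higher and 1 lower with a median of 0.94. TAC1, GEM, CALCB, RGCC and FABP4 were 43.4-, 31.3-, 29.2-, 20.6- and 19.8-fold lower. Capillary genes had 4 of 7 lower with a median of -1.72. Cardiomyocyte-like cells, in cluster 17, had TNNT2, cardiac troponin T, in 90.5% (85.7 to 94.1) and the myosin gene MYH6 in 77.7% (71.5 to 83.2) after thinning, against 1.25% and 0.357% of endothelial-like and 0.894% and 0.437% of mesenchymal-like cells. Without thinning these cardiomyocyte shares were 95.6% and 87.8%, at a median depth of 3253 UMIs against 3272.5 and 4195 UMIs in the endothelial-like and mesenchymal-like cells of that library.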

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

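The test of a library-wide difference in handling, given last, was chosen only after the result was seen. The other tests were written down before their results.

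Chip against well went opposite ways at day 10 and day 17 for 1 gene list and 4 genes, and these differences were not tested, since each group has 1 library. Both day 17 chip libraries were set against the same well library, so their ratios are not independent. The inflammation list in endothelial-like cells had a median log2 ratio of 0.40 at day 10, and of -0.73 under low flow and -0.59 under high flow at day 17. The chemokine CXCL2 had 1.15, -1.79 and -1.31, the transcription factor CEBPD 1.01, -1.65 and -1.40, and the chemokine CCL2 1.07, -2.53 and -1.99. Levels of these genes rose in wells between the days. From day 10 to day 17 in wells, endothelial CXCL2 went from 16.3 to 163 CPM, CEBPD from 11.1 to 38.0 and CCL2 from 41.6 to 156 CPM. On chip CXCL2 went from 36.3 CPM to 47.0 under low and 65.7 under high flow. CEBPD fell there from 22.4 CPM to 12.0 and 14.3, and CCL2 from 87.1 CPM to 26.9 and 39.3. At day 10 CCL2 stood at 41.6 CPM in wells and 87.1 CPM on chip in endothelial-like cells, and at 48.2 and 124 CPM in the other cells. RNA from other cells was not excluded as the source of its day 10 ratio. In mesenchymal-like cells CHAC1, a stress-response gene, had 1.47, -2.01 and -2.17.

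Endothelial-like cells of both day 17 chip libraries had a lower cell cycle list than those of the well library. If cycling mesenchymal cells caught as doublets in the well library were the cause, leaving out cells with 3 or more UMIs of mesenchymal markers would bring the medians near 0. The median nearer to 0, under low or high flow, was still -1.44. This argues against doublets with 3 or more such UMIs as the whole cause, while doublets with fewer would pass the filter. The filter kept 542 of 623 well cells, with 4719262 of 6649796 UMIs, and 358 of 368 low-flow and 371 of 388 high-flow cells. The cells left out here do count in the day 17 endothelial comparisons above. Well cells were deeper at the median than low-flow cells (8167 against 6427 UMIs) but not than high-flow cells (8827 UMIs). Deeper cells in the well library are also argued against by thinning. After it, the lower bound of the well share of TOP2A cells exceeded the highest chip bound by 2.70 percentage points. Flow, the chip itself and other differences between single libraries may each contribute and remain untested.

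Glycolysis genes were lower in mesenchymal-like cells under high than under low flow. A heat shock response in the low-flow library was examined in cells without a UMI of HSPA1A, HSPA1B or DNAJB1 (3592 high-flow and 1650 low-flow cells), where the list median was still -1.25. A different mix of the same clusters was examined by cluster, and 0 of 11 high-flow clusters had a summed glycolysis level above the lowest of the 10 low-flow clusters. Both explanations are thereby argued against as the whole cause. The flow rate itself, the kit or handling may be the source, and with 1 VNO library per flow rate these were not tested. As given above, the list was also lower in high-flow VNOs than in wells, and higher in heart organoids under high flow. ENO1 stood at 402 CPM in high-flow VNOs, 986 in heart organoids, 1225 under low flow and 1338 in day 17 wells. The low level was thus seen in the high-flow VNO library and not in both high-flow libraries. Organoid type differs between these, so flow rate remains undecided.

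Immediate early and laminar flow genes were lower in endothelial-like cells of the heart organoid library than of high-flow VNOs. For KLF2 and KLF4 of the laminar flow list, shallower cells are argued against. After thinning, the smaller gap between the intervals over these genes was 4.94 percentage points. No gene of the immediate early list was thinned, so depth was not examined for that list. A library-wide difference in dissociation or handling would lower the same lists in other cells too. In mesenchymal-like cells the medians were -0.66 for immediate early genes and -1.05 for laminar flow genes, consistent with such a difference. A difference between the organoid types themselves may act in all cells as well and remains open, because organoid type and library are the same here.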

How the results depend on the processing

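No paired analysis was possible because each group has 1 library. This limits every comparison, and the endothelial-like classes held 276 to 1515 cells. The joint clustering gave no value for the mesenchymal-like class at day 6, which had under 50 cells in it. Of its 22 clusters, 10 took 75% or more of their cells from 1 library, and 9 of these were among the 15 mesenchymal-like clusters or clusters kept out of that class for their leading genes. One alternative, keeping clusters with leading genes of another type in the mesenchymal-like class, was chosen after the data had been seen.

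The endothelial share stayed inside its interval in 37 of the values under alternatives and moved in 19. The stricter cell filter gave 7.69% at day 6, 15.2% at day 10 in wells and 3.49% in the heart organoid library. The looser filter gave 12.0% at day 6, 15.3% and 8.08% at day 10 in wells and on chip, 5.09% under low flow, 4.00% under high flow and 4.88% in the heart organoid library. Without doublet removal the share was 17.3% and 7.81% at day 10 in wells and on chip and 5.33% in the heart organoid library. Joint clustering gave 11.2% at day 6. Naming each cell by itself gave 10.1% at day 6, 8.64% at day 10 on chip, 6.43% in wells at day 17, 4.30% under high flow and 8.47% in the heart organoid library. Resolution 2 gave 2.44% in wells at day 17. The cause was not tested.

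Counts of genes passing moved with the thresholds by construction. They are given in the order day 10 chip against well, low flow against well, high flow against well, high against low flow, day 10 well against day 6, day 17 against day 10 well, low flow against day 10 chip, high flow against day 10 chip, and heart organoid against high flow. Endothelial counts were 365, 814, 933, 664, 1137, 1050, 1413, 1526 and 1589 at 5 CPM, and 27, 45, 71, 45, 139, 98, 127, 139 and 177 at 100 CPM. They were 571, 916, 1129, 939, 1404, 1223, 1589, 1953 and 1838 at 1.5-fold, and 28, 84, 85, 51, 207, 156, 210, 227 and 238 at 3-fold. Mesenchymal counts were 194, 735, 485, 626, 1514, 971, 1450, 1358 and 1371 at 5 CPM, and 15, 69, 45, 71, 154, 106, 145, 116 and 139 at 100 CPM. They were 255, 899, 789, 722, 1545, 1201, 1675, 1759 and 1798 at 1.5-fold, and 15, 107, 57, 92, 324, 165, 201, 160 and 194 at 3-fold. With the class from the joint clustering, the mesenchymal counts were 427 for high flow against well (134 higher, 293 lower) and 424 for high against low flow (156 higher, 268 lower), and the cause was not tested. Under the other alternatives the counts stayed within 1.5 times, in 63 endothelial and 69 mesenchymal values.

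Median-of-ratios scaling moved the median of all genes by 0.12 for high flow against day 10 chip in endothelial-like cells, and by 0.12 and 0.13 for low and high flow against day 10 chip in mesenchymal-like cells. With it, higher genes went from 38.3% to 52.8% of those passing in the first of these comparisons, and from 42.0% to 53.2% and from 42.8% to 60.2% in the others. It also moved that share from 46.8% to 56.8% for day 17 against day 10 wells in endothelial-like cells. Leaving out mitochondrial and ribosomal protein genes moved it from 40.2% to 50.4% for the heart organoid comparison in endothelial-like cells. Of the genes passing, 79.9% to 100% passed in the same direction with median-of-ratios scaling, 72.2% to 95.3% when CPM was averaged over cells, 49.7% to 99.1% with the joint clustering and 73.4% to 100% without cells carrying markers of the other class. Without cells that had a proliferation marker 58.6% to 95.1% did, and 1 gene passed in the opposite direction. The range was 77.4% to 96.6% with kept-out clusters included, 91.7% to 100% without mitochondrial and ribosomal protein genes and 96.3% to 100% with 2 added to each count.

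Without cells that had a proliferation marker, 3 list medians changed sign among those outside the random-list range and at least 0.5 in size. Sign changes of other medians were not counted. The endothelial cell cycle median of day 10 chip against well was 0.15, by construction of that setting. For day 10 wells against day 6 in mesenchymal-like cells, the interstitial matrix median went from 0.75 to -0.24 and the HOX median from -0.67 to 0.14, and the cause was not tested. Of the other list values under alternatives, 4228 moved by at most 0.5 times the width of the central 95% of matched random lists. Another 184 moved by more. Log2 ratios of named genes stayed within their interval in 1501 values and moved in 390, with no change of sign. The mesenchymal share moved in 53 of its values. With joint clustering it went from 24.7% to 0.404% at day 6, from 81.9% to 22.5% in wells at day 17 and from 77.0% to 38.4% under low flow. It was also 7.88% with the looser filter and 11.4% at resolution 0.5 at day 6. The cause was not tested. The shares of cells with a UMI moved in 238 values.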

Other observations

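Small clusters outside the vascular classes carried genes of other lineages. Clusters with PAX2, PAX8, LHX1 and EMX2, transcription factors of early kidney tubules, were present at day 10 in wells (170 cells, 1.80% of kept cells) and on chip (413 cells, 3.42%), under low flow (39 cells, 0.485%), under high flow (77 cells, 0.707%) and in the heart organoid library (289 cells, 1.72%). Day 17 wells had no such cluster of their own, but such cells were not absent there. Joint cluster 20, with the same leading genes, held 42 of their cells, 37 under low flow and 69 in day 10 wells. In the low-flow cluster PAX2 stood at 145, PAX8 at 33.8, LHX1 at 165 and EMX2 at 37.1 CPM, against 0.547, 0.291, 3.20 and 1.59 CPM in the other cells. In the day 10 chip cluster PAX2 stood at 156 CPM against 2.70 CPM in the other cells, and LHX1 at 274 against 7.46 CPM. Clusters with SOX2, CDX2, PAX3, ZIC2 and CDH6, genes of the posterior neural tube and tail bud, held 600 cells (4.96%) at day 10 on chip and 762 cells (4.52%) in the heart organoid library. In the latter SOX2 stood at 210.0 against 4.05 CPM and CDX2 at 198 against 5.75 CPM. A low-flow cluster of 148 cells (1.84%) had CDH6 at 423 and PAX3 at 90.0 CPM, with CDX2 at 4.41 CPM. A neural crest-like cluster with ERBB3, FOXD3 and SOX10 held 69 cells (0.571%, 0.445 to 0.722) at day 10 on chip. These genes were chosen after their values had been seen, from the leading genes of the clusters.

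Cardiomyocyte-like cells of the heart organoid library had 2604 CPM of TNNT2 (2522 to 2688), 1415 CPM of MYH6 and 2209 CPM of MYL7, an atrial myosin light chain, beside 4.66, 2.04 and 3.23 CPM in the other cells. The ventricular myosin gene MYL2 stood at 22.4 CPM (15.4 to 31.4) and MYH7 at 50.1 CPM. Genes listed as atrial went both ways against the other cells. NPPA and SLN stood at 178 and 163 CPM against 0.540 and 0.600 CPM, but NR2F1 and NR2F2 at 50.1 and 102 against 175 and 369 CPM. IRX4, listed as ventricular, stood at 46.1 against 0.516 CPM. The cells were therefore not named atrial or ventricular. PLN, which regulates the calcium pump, stood at 1960 CPM, RYR2 at 83.3 CPM and NKX2-5, a cardiac transcription factor, at 371 CPM. The pacemaker channel gene HCN4 stood at 15.6 CPM (9.88 to 23.4). In mural-like clusters MGP stood at 6.70 and 12.0 CPM at day 10 in wells and on chip, at 493, 1749 and 595 CPM at day 17 in wells, under low flow and under high flow, and at 167 CPM in the heart organoid library.

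Summed HOX levels in mesenchymal-like cells were 784 CPM at day 6, 542 and 633 CPM at day 10 in wells and on chip, 227, 316 and 174 CPM at day 17 in wells, under low flow and under high flow, and 700.3 CPM in the heart organoid library. The fall from day 6 to day 10 in wells was not kept in all settings. The median log2 ratio of the list was -0.67 with all cells of the class and 0.14 without cells that had a proliferation marker. Summed glycolysis levels in endothelial-like cells at day 17 were 7728 CPM in wells, 9917 CPM under low flow and 5486 CPM under high flow.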
